A study of Mus musculus with 13 samples.

How the data were processed

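The series holds 13 samples of mouse embryonic fibroblasts of the genotype Mbnl1-/-/Mbnl2-/-, and 6 reactivity profiles were analysed. Per the labels, MBNL1 was induced with 1 ug/mL doxycycline for 18 to 20 hours, and cells were probed for 12 minutes with NAI at 100 mM, or mock-treated with DMSO, and total RNA was then extracted. Profiles were used for 3 induced and 1 uninduced NAI sample of the Mbnl1 amplicon, grouped by their sample titles, and for Rn7SK and Rpph1. The labels tie each control RNA profile to both an NAI and a DMSO sample, so it is treated as 1 value of the authors per nucleotide, with no replicate. A second uninduced NAI sample and the DMSO samples were not used here on their own.

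Each profile gives, per nucleotide, a SHAPE reactivity and a standard error, both read as a score in the unit the authors deposited, and a code of -999 for nucleotides without a value. The mutation-counting tool, its version, the normalization of the reactivities, the DMSO sample set against each NAI sample and the formula of the standard error are not given in the sources used here. Values below 0 occur, as subtraction of a background would leave. They made up 18.9% of nucleotides in the uninduced Mbnl1 profile, 8.58 to 12.8% in the induced ones, 23.6% in Rn7SK and 26.0% in Rpph1. Build mm10 is named per the submitters' processing notes. Read depth is unknown, so no counting interval is given. No pair of Mbnl1 profiles shared an identical value among 407 nucleotides, so no profile was a copy of another. In Rpph1, 2 nucleotides had both a reactivity and an error of 0 and were kept.

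Sequences in the profiles were matched to GRCm38 (mm10) and read against the GENCODE M21 annotation; the 54-nt exon is number 3, 4, 5 or 6 in 5 annotated Mbnl1 transcripts. For comparisons between groups, each Mbnl1 profile was divided by its own mean after clipping at its 5th and 95th percentiles, so that 1 is the profile mean; levels are printed as deposited and changes in these relative units, where marked. Nucleotides measured in all 4 Mbnl1 profiles (407) were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend), induced minus uninduced, with Benjamini-Hochberg adjustment and a threshold of 0.05. With 1 uninduced profile, limma assumes that it varies as the induced ones do. Means of windows of 25 nt were tested the same way.

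Motif lists, annotated features and predicted pairing were tested two-sided with an exact permutation in which the list is shifted around the measured nucleotides through every position, keeping the spacing of the list (1 shift per measured nucleotide: 407 where the Mbnl1 profiles are compared, smallest p 0.00246; for predicted pairing 407 to 409 in the Mbnl1 profiles, 313 in Rn7SK and 315 in Rpph1, smallest p 0.00319 and 0.00317). Differences between bases, and motifs against nucleotides of matched base, used 100000 random permutations. Structures were predicted with ViennaRNA 2.7.2, as the minimum free energy structure of the sequence alone, or as a partition function with reactivities as Deigan pseudo-energies (slope 1.8, intercept -0.6), where negative reactivities added no energy. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

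Lists, tests, alternatives and the rule for nucleotides named in the text were fixed before the data were examined, except where the text says otherwise. The 7 lists were YGCY, UGCU, GCUU, runs of 4 or more U, CUG, CAG and GC outside YGCY. The rule named up to 20 nucleotides past the threshold; where fewer than 10 passed, it added the 5 largest rises and 5 largest falls at which the uninduced value lay outside all induced values by more than 1.96 deposited standard errors. It also named the 2 largest rises and falls among motif sites, each window past the threshold, and in each control RNA the 5 most reactive nucleotides with a standard error below a fixed part of the reactivity and the longest run below 0.4. Alternatives covered the scaling, negative values, end nucleotides, deposited errors, leaving out each induced replicate, weights, the variance trend, the log2 scale, window sizes, motif definitions, summary statistics, folding settings and a call in the style of deltaSHAPE.

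The nucleotide fit was tested on simulated data made from the observed means and spread, in 10 simulations of 407 nucleotides. Over all 10, 400 changes were planted. The noise was normal with an SD set by the mean alone, and the lone profile was given the same noise as the others. Of the nucleotides called there, 7.05% were unchanged ones, and the estimated changes were off by -0.0132 on average. Such rates depend on the noise and on the share of changed nucleotides, which is unknown in the data. The circular-shift test of YGCY gave p under 0.05 in 4% of draws with no change and in 59% of draws with a planted change of 0.3.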

Results

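SHAPE-MaP profiles were analysed for 3 mouse RNAs probed inside living fibroblasts. SHAPE-MaP treats cells with a reagent, here NAI, that acylates the 2′-hydroxyl of flexible nucleotides. Reverse transcription then reads the adducts as mutations. A high reactivity thus marks a nucleotide that is free to move and a low one a nucleotide held by base pairing, stacking or a bound protein. The cells were embryonic fibroblasts lacking Mbnl1 and Mbnl2, which encode RNA-binding splicing regulators, with MBNL1 expression that could be switched on by doxycycline. The target was a stretch of the Mbnl1 pre-mRNA, and the question, per the series description, was the structure of a regulatory region in a scarce pre-mRNA and the proteins it meets. The values were 3 profiles of the Mbnl1 region from induced cells (doxycycline at 1 ug/mL for 18 to 20 hours), 1 profile from uninduced cells, and 1 profile each of the abundant RNAs Rn7SK and Rpph1. The labels do not say whether the numbered sets are separate cultures. The limma p-values thus rest only on the spread between the 3 induced profiles, which may be technical. The permutation p-values compare nucleotides along the sequence and measure no spread between samples. With 1 uninduced profile, its own spread is unknown throughout.

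The Mbnl1 region of 459 nucleotides (nt) lies on chromosome 3, 60614481 to 60614939, plus strand (mm10). It holds a 54-nt exon at nt 203 to 256 (60614683 to 60614736), 202 nt of the upstream intron and 203 nt of the downstream intron. Rn7SK, the small nuclear RNA that holds the elongation factor P-TEFb inactive, is covered by 331 nt of chromosome 9, 78175303 to 78175633, minus strand. Rpph1, the RNA subunit of RNase P, is covered by 319 nt of chromosome 14, minus strand. Its sequence matched 50807450 to 50807768, 1 nt away from the annotated 50807449 to 50807767. Part of it overlaps a first exon of Ccnb1ip1 on the same strand. Values were present for 407 to 409 nt of the Mbnl1 region (nt 26 to 436), 313 nt of Rn7SK and 315 nt of Rpph1. Reactivities below 0.4 made up 58.5% of nucleotides in the uninduced Mbnl1 profile and 58.4 to 59.2% in the induced ones, against 65.8% in Rn7SK and 71.1% in Rpph1. The read depth is unknown. The authors' median standard error was 0.00127 to 0.00153 in the Mbnl1 profiles, 0.0225 in Rn7SK and 0.0640 in Rpph1. Between the 3 induced profiles the median SD of a nucleotide was 0.101, and the median ratio of that SD to the deposited standard error was 71.4, so the deposited error was not used in the tests between groups, only in the rule that names nucleotides and in some alternatives.

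The Mbnl1 region kept the same overall pattern of reactive and protected nucleotides with and without MBNL1, and the uninduced profile stood somewhat apart. Across the 407 nt measured in all 4 profiles, Pearson's r was 0.868 to 0.910 (Spearman's rho 0.852 to 0.884) between induced profiles and 0.756 to 0.773 (rho 0.804 to 0.817) between an induced profile and the uninduced one. Neighbouring nucleotides are not independent replicates, and each r was tested by an exact circular-shift permutation test, one-sided for a high r. This permutation test gave p = 0.00246 for all 6 pairs, the smallest p that 407 shifts allow (Benjamini-Hochberg adjusted 0.00246). The uninduced value lay outside the range of the 3 induced values at 264 nt (64.9%, where chance gives 50%). For an induced profile set against the other 3 profiles this share was 42.5 to 48.4%. Every nucleotide has a highest and a lowest profile, so the shares of the 4 profiles have a fixed sum. The lower induced shares thus follow from the uninduced one and are no separate comparison. The mean r of the induced pairs exceeded that of the mixed pairs by 0.128, and by 0.0606 without nt 63, an alternative chosen after seeing the data.

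**Figure D1:**
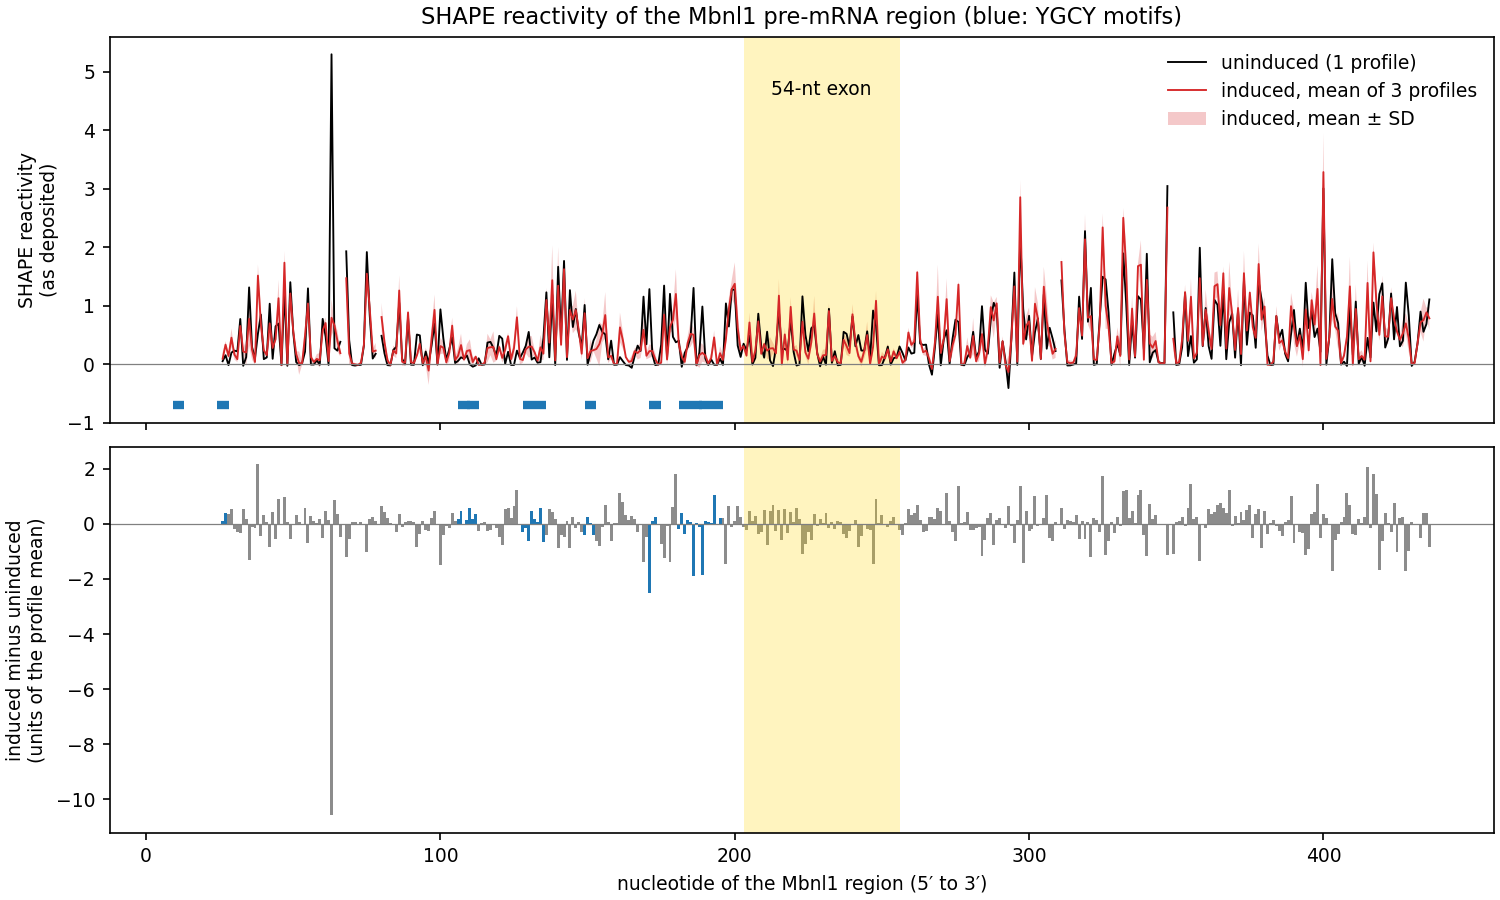
SHAPE reactivity as deposited (upper panel, y axis, no unit) and its change on induction in units of the profile mean (lower panel) along the 459 nt of the Mbnl1 region (x axis), with the uninduced profile in black, the mean of 3 induced profiles in red with a band of 1 SD, the exon in yellow and YGCY motifs in blue. The profiles share most peaks, and nt 63 differs most, with 5.30 in the uninduced profile against a mean of 0.797 in the induced ones.

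A single nucleotide, an adenosine of the upstream intron, passed the test between the uninduced profile and the induced ones. Which nucleotides were called, and how many, depended on the settings. A63 (60614543) had a reactivity of 5.30 in uninduced cells and 0.797 ± 0.314 (SD, n = 3) in induced cells; relative to each profile's mean it fell by 10.6 (SE 0.810), with an adjusted p of 0.00388 in limma with Benjamini-Hochberg adjustment over 407 nt. The next largest falls lay in YGCY motifs just upstream of the exon and did not pass with all profiles: U171 (60614651) had 1.29 uninduced and 0.225 ± 0.115 (n = 3) induced, adjusted p = 0.0956 in limma; G186 (60614666) had 1.31 and 0.506 ± 0.111; G189 (60614669) had 0.987 and 0.196 ± 0.151, with adjusted p of 0.222 and 0.169 in limma. U171 passed in limma with rank-based scores (adjusted p = 0.00531), without induced replicate 1 (0.000243) and without replicate 3 (0.0112), and G189 without replicate 3 (0.00848). Without replicate 2 the adjusted p in limma was 0.447 for both, with changes of -2.49 and -1.93 (-2.49 and -1.86 with all profiles), and on the log2 scale it was 0.320 and 0.523. A428 (60614908) in the downstream intron, also short of the threshold, had 1.40 uninduced and 0.699 ± 0.176 induced. The 5 largest rises did not pass either, with adjusted p of 0.239 to 0.466 in limma: A38 (0.525 uninduced, 1.52 ± 0.192 induced), G415 (0.453 and 1.39 ± 0.382), U417 (1.06 and 1.91 ± 0.166), G180 (0.377 and 1.20 ± 0.422) and G325 (1.497 and 2.34 ± 0.239). Of these, G415 passed in limma without induced replicate 1 (adjusted p = 0.0181) and had 0.575 without replicate 2. At an unadjusted p under 0.05, limma gave 45 nt, of which 31 were lower and 14 higher on induction, where 20.35 would fall there by chance. The balance was the reverse among the 257 nt at which the uninduced value lay outside all induced values by the margin of the naming rule. There, 148 were higher and 109 lower on induction. The mean absolute difference of the uninduced profile from the other 3 was 0.457 of the profile mean. With an induced profile as the lone one it was 0.319 to 0.346. The uninduced profile is then among the other 3 and adds to their spread, so these values are no separate reference. The A63 call rests on 1 uninduced profile, and its adjusted p in limma was 0.339 without induced replicate 2, 0.0524 with negative values set to 0, 0.0555 without the variance trend and 0.320 on the log2 scale. The change itself stayed at -10.6 without replicate 2, -10.5 with negative values set to 0 and -10.6 without the trend, so the call ended there without a smaller change. Simulations held 400 planted changes over 10 runs and let the lone profile vary as the induced ones do. In them, a planted fall of 1 profile mean was recovered at 31% of nucleotides and a fall of 2 at 72%. Rises of those sizes were recovered at 6% and 36%. These rates hold for that setting, which may differ from the data in the share of changed nucleotides and the spread of the uninduced profile.

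In windows of 25 nt, limma called 2 of 17. Reactivity in nt 351 to 375 (60614831 to 60614855), a U-rich part of the downstream intron, rose by 0.326 of the profile mean on induction (SE 0.107, adjusted p = 0.0369 in limma), from 0.597 to 0.769 ± 0.0314 (SD, n = 3). The window of nt 51 to 75 (60614531 to 60614555) fell by 0.477 (SE 0.0854, adjusted p = 5.04e-05 in limma), from 0.565 to 0.376 ± 0.0416. The fall came from A63, since without that nucleotide the window had 0.359 uninduced and 0.358 ± 0.0405 induced (adjusted p = 0.809 in limma). The rise in nt 351 to 375 lost its call without each induced replicate in turn (adjusted p of 0.140, 0.130 and 0.103 in limma) and without nt 63 (0.0619, with a change of 0.320). The rise kept its call with rank-based scores and with high-error nucleotides left out. In windows of 10 nt limma called 2 of 42, both lower in induced cells. These were nt 61 to 70, which holds A63, and nt 181 to 190 within the YGCY motifs (-0.373, adjusted p = 0.0269 in limma). The latter fall came from G186 and G189, with changes of -1.91 and -1.86 of the profile mean. The other nucleotides of that window changed by -0.359 to 0.389.

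MBNL proteins bind YGCY (Y, C or U), and all 12 such sites of the region lay in the upstream intron, 11 of them measured at least in part. The sites did not move one way on induction: 4 had a lower mean reactivity in every induced profile than in the uninduced one, 4 a higher one, and 3 lay between. The largest falls were UGCC at nt 171 to 174, from 0.360 to 0.133 ± 0.0308 (SD, n = 3), and CGCU at nt 185 to 188, from 0.490 to 0.293 ± 0.0767. The largest rises were UGCU at nt 192 to 195, from 0.0400 to 0.187 ± 0.0290, and UGCC at nt 109 to 112, from 0.0223 to 0.160 ± 0.0281. Both started near 0, as G193 and C194, and G110, C111 and C112, were below 0 in the uninduced profile. That profile had more nucleotides below 0 (18.9%) than the induced ones (8.58 to 12.8%). Whether this difference made the rises was not tested. No single site was tested. Over the 40 measured motif nucleotides, 14 lower and 26 higher on induction, the change relative to the rest was -0.0662 of the profile mean, with p = 0.612 in an exact circular-shift permutation test (0.857 adjusted over 7 lists). With limma, 2 motif nucleotides, U171 and G189, had an adjusted p under 0.05 when adjusted over the list alone (0.0188 and 0.0497), and 0 over all nucleotides tested. The changes of the other lists did not pass the test: UGCU sites 0.120 (p = 0.393), GCUU sites -0.0327 (p = 0.8501), runs of 4 or more U 0.0599 (p = 0.590), CUG 0.152 (p = 0.201), CAG -0.160 (p = 0.560) and GC outside YGCY -0.00594 (p = 0.978), each by the exact permutation test; 0 nucleotides passed in any of them when adjusted over the list alone. Within the U runs, the U from the third to the last but 1 averaged 0.0740 uninduced and 0.0886 ± 0.0189 (SD, n = 3) induced.

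**Figure D2:**
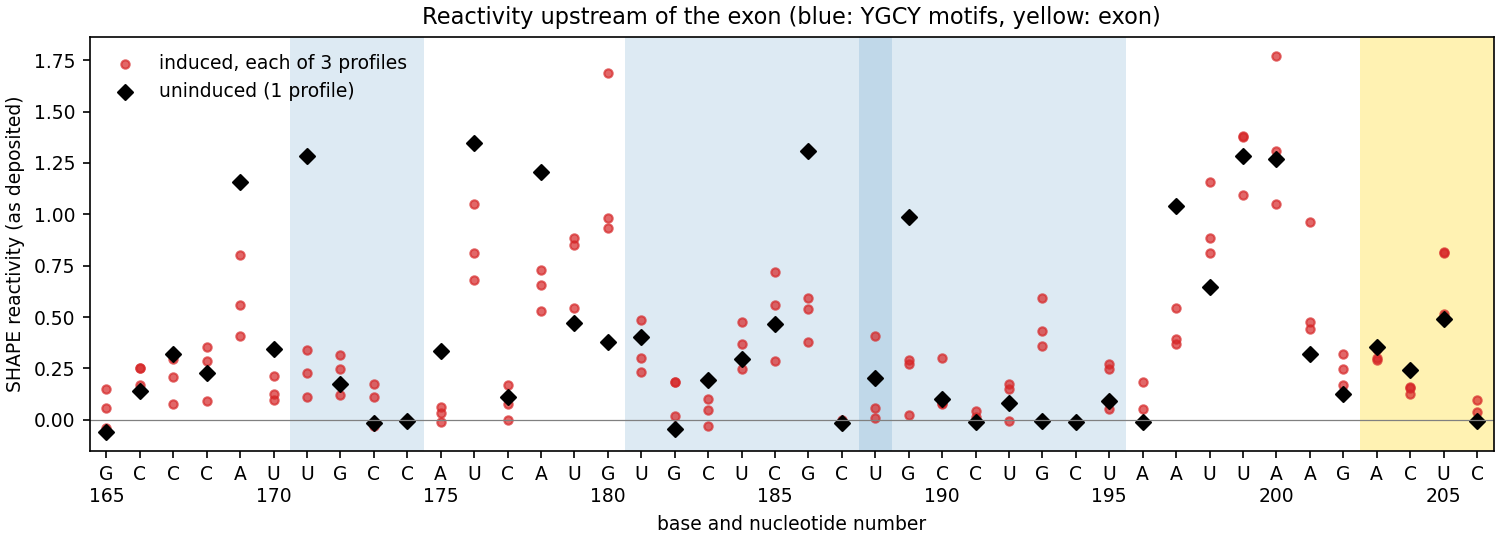
SHAPE reactivity as deposited (y axis, no unit) of each nucleotide from nt 165 to 206 (x axis), with the uninduced profile as black diamonds, each of the 3 induced profiles as red points, YGCY motifs in blue and the start of the exon in yellow. At U171, G186 and G189 the uninduced values of 1.29, 1.31 and 0.987 lie above all 3 induced values, which did not pass the test over all nucleotides.

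Within each profile, YGCY nucleotides had a lower mean reactivity than the rest of the region, with and without MBNL1, though not past the threshold after adjustment over all lists. Their mean was 0.236 against 0.484 elsewhere in uninduced cells, and 0.211 ± 0.0289 (SD, n = 3) at the motifs in induced cells. The differences were -0.247 in the uninduced profile (p = 0.0467) and -0.312, -0.257 and -0.293 in induced replicates 1 to 3 (p = 0.0221, 0.0565 and 0.0344), by exact circular-shift permutation tests. Adjusted over 28 tests of 7 lists, the permutation p was 0.0885 to 0.144. GC dinucleotides outside YGCY were as low or lower, at 0.137 uninduced and 0.131 ± 0.0532 induced, with adjusted p of 0.0688 to 0.0860 in the same permutation tests. Part of the motif difference followed from its bases: random nucleotides of matched base gave -0.101 in the uninduced profile, and against them p was 0.0537 there and 0.00799, 0.0254 and 0.00876 in the induced replicates (100000 permutations; adjusted over the 4 profiles 0.0537, 0.0175, 0.0339 and 0.0175). The matched permutations drew single nucleotides and did not keep neighbours together, as the circular shifts do. Their p-values can thus be too small where neighbouring nucleotides are alike. No test compared this motif difference between the groups beyond the change given above.

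No annotated part of the region passed the test for a change on induction. Mean reactivity of the exon was 0.319 uninduced and 0.305 ± 0.0104 (SD, n = 3) induced. The upstream intron had 0.392 and 0.369 ± 0.0194, and the downstream intron 0.569 and 0.620 ± 0.00549. The upstream intron holds A63. Its change relative to the rest was -0.123 of the profile mean, and -0.0611 without nt 63, an alternative chosen after seeing the data. The 20 nt after the 5′ splice site (60614737 to 60614756) had 0.352 and 0.466 ± 0.0414, and the 50 nt before the 3′ splice site (60614633 to 60614682) 0.380 and 0.343 ± 0.0286. Over 7 features the exact circular-shift permutation p of the change was 0.125 to 0.644, and 0.542 to 0.644 after adjustment.

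Pairing was then modelled by folding the region with each profile as a guide. YGCY nucleotides were paired with a mean probability of 0.684 with the uninduced profile and 0.702 ± 0.0405 (SD, n = 3) with the induced ones, a difference smaller than the spread between induced profiles. Other nucleotides had 0.406 and 0.422 ± 0.0187. The comparison at the motifs depended on the setting: with slope 2.6 and intercept -0.8 the uninduced profile gave 0.639, below all 3 induced ones (0.741 ± 0.0439, SD, n = 3), a difference larger than their spread. Without reactivities the sequence gave 0.608 at the motifs and 0.564 elsewhere. These are outputs of a folding model, not measurements.

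In the control RNAs, nucleotides predicted unpaired from the sequence had a higher mean reactivity than those predicted paired, a difference that passed the test only before adjustment. The authors' values averaged 0.655 over 121 unpaired and 0.331 over 192 paired nucleotides of Rn7SK, and 0.661 over 106 and 0.320 over 209 of Rpph1. The exact circular-shift permutation p was 0.0128 in Rn7SK and 0.0190 in Rpph1, 0.0571 for both after adjustment over 6 profiles, with areas under the ROC curve of 0.639 and 0.632. In the Mbnl1 region the same prediction did not separate the nucleotides: 0.460 unpaired and 0.459 paired in the uninduced profile (permutation p = 1.00), and differences of 0.0267 to 0.0295 in the induced ones (permutation p of 0.578 to 0.643; ROC areas 0.467 to 0.522 over the 4 profiles). Whether the RNAs differ in this respect was not tested. The most reactive Rn7SK nucleotides in the authors' profile were G314 (6.20), C131 (5.70), G111 (5.40), A126 (3.48) and U57 (3.35), all but G314 predicted paired, and its longest run below 0.4 was nt 24 to 39. Those of Rpph1 were C316 (9.20), A10 (5.02), U158 (4.21), U42 (4.07) and U310 (3.89), of which C316 and U310 were predicted paired, with the longest low run at nt 22 to 39.

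**Figure D3:**
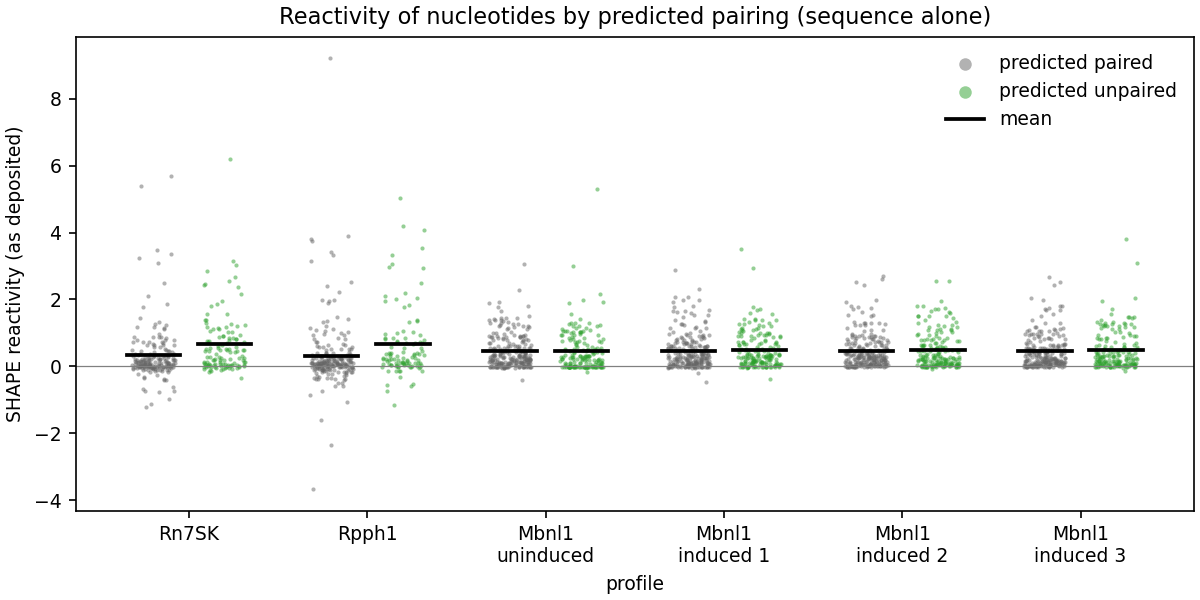
SHAPE reactivity as deposited (y axis, no unit) of every measured nucleotide in each of 6 profiles (x axis), split into nucleotides predicted paired (grey) and unpaired (green) from the sequence alone, with black lines at the means. Unpaired nucleotides average 0.655 against 0.331 in Rn7SK and 0.661 against 0.320 in Rpph1, while the Mbnl1 means nearly coincide.

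Adenosines were the most reactive base of the Mbnl1 region and cytidines the least. Mean reactivity was 0.716 for A, 0.572 for G, 0.428 for U and 0.190 for C in the uninduced profile. In the induced profiles it was 0.657 ± 0.0357, 0.600 ± 0.0300, 0.459 ± 0.0125 and 0.205 ± 0.0182 (SD, n = 3). The means of A include A63 (5.30 uninduced, 0.797 ± 0.314 induced), and the higher uninduced mean of A leans on that nucleotide. Rn7SK had the same extremes in the authors' profile, 0.920 for A and 0.203 for C. The bases differed in these 5 profiles with a permutation p of 1e-05, the smallest that 100000 permutations give (1.2e-05 adjusted). In Rpph1 U had the highest mean, 0.748, and G the lowest, 0.334, and the difference between bases did not pass (permutation p = 0.102); p was 0.0116 when medians were compared.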

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

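Leaving out nt 63, the leave-one-out and Spearman values of the profile agreement were chosen after seeing the data. No paired analysis was possible because the groups compared share 1 set number, there being 1 uninduced profile. Against 1 nucleotide called in limma (0 higher, 1 lower), rank-based normal scores called 7 (5 higher, 2 lower), the log2 scale 3 and the deltaSHAPE-style call, which uses the deposited errors, 90 (37 with the SD between induced profiles as the error); setting negative values to 0, leaving out the 10% with the highest standard error, dropping the trend or leaving out nt 63 called 0. Without induced replicates 1, 2 and 3 the counts were 12, 0 and 7. Of the 2 windows called, the rise from nt 351 alone was called with normal scores and with high-error nucleotides left out. A fall from nt 426 was called as well with scaling on the 90th to 98th percentile, negative values set to 0 or the ends left out. The count was 0 without nt 63 and 0 in windows of 50 nt, and leaving out an induced replicate gave 0 to 2. The count stayed at 2 without induced replicate 2 and in windows of 10 nt, but all were falls (from nt 51 and 426, and from nt 61 and 181) and the rise was not called. The change at YGCY turned positive with normal scores (0.0173), for UGCU alone (0.120) and with medians (0.0222), passing the threshold in none. The lower YGCY reactivity lost its unadjusted call with 2 flanking nt (-0.181 uninduced, -0.221 and -0.234 in induced replicates 1 and 3) and with medians (-0.199, -0.167 and -0.189). Induced replicate 2 had no call to lose, and its difference was -0.205 with flanking nt and -0.0694 with medians. Against matched bases the uninduced difference of -0.247 lost the call and that of induced replicate 2, -0.257, gained it. In induced replicate 3 it was also lost for UGCU alone (-0.299) and for the GC core (-0.295). The gap in r of 0.128 was 0.0666 without high-error nucleotides, 0.0817 without the most reactive 5%, 0.0606 without nt 63, 0.0591 for Spearman's rho and 0.104 to 0.153 without an induced replicate. The difference by predicted pairing in the uninduced profile turned to -0.0140 with a probability cutoff and -0.00836 without lonely pairs. Bases of Rpph1 differed by 0.411 without the ends and 0.202 in medians, both past the threshold. The induced minus uninduced pairing probability moved to 0.102 with slope 2.6 and intercept -0.8, past the spread between induced profiles. Without nt 63 the change of the window from nt 51 went from -0.477 to -0.0416, while that from nt 351 was 0.320 in place of 0.326 and lost its call in adjusted p alone; the cause of the other changes was not tested. Among results that answer a comparison, the other 162 recomputed values kept their direction and side of the threshold, moved by less than the spread or, for counts, stayed close to the count first given, which does not show that the same windows were called. Unknown depth limits them all.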

Other observations

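Of the tests below, the gap in mean r over all nucleotides and the mean change of the 50 nt upstream of the exon, also without high-error nucleotides, were planned. The others were chosen after the patterns were seen, and all of these but 3 after the values they rest on; those 3 are the lone-profile and leave-one-out counts upstream of the exon and the pairing of inner U.

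The downstream intron holds a tract of U and G at nt 309 to 383 (60614789 to 60614863) whose G and U had different levels; it is the stretch that scores highest with 1 for each G or U and -2 for each A or C, a rule chosen after seeing the data. Its 17 measured G averaged 1.11 in the uninduced profile and 1.27 ± 0.0987 (SD, n = 3) in the induced ones, against 0.414 and 0.403 ± 0.0114 for the 58 G elsewhere. Its 54 U averaged 0.453 and 0.511 ± 0.0132, close to the 0.416 and 0.436 ± 0.0126 of other U. For G, the exact circular-shift permutation p was 0.0133, the smallest that shifts over 75 G allow, in 3 profiles and 0.0267 in induced replicate 2 (adjusted over 12 tests 0.0241 and 0.0400); for U it was 0.497 to 0.783.

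Inside runs of U the reactivity nearly vanished in every Mbnl1 profile. Over 13 runs of 4 or more U, the first U averaged 0.754 uninduced and 0.746 ± 0.00930 (SD, n = 3) induced, the second 0.631 and 0.740 ± 0.0374, the 24 inner U 0.0740 and 0.0886 ± 0.0189, and the last 0.364 and 0.385 ± 0.0712; the bases just before the runs averaged 1.17 and 1.25 ± 0.164 and those just after 1.14 and 1.19 ± 0.0826. How far the inner U and the bases beside the runs belong to the tract of U and G above was not examined. Inner U were lower than the rest of the region in all 4 profiles (exact circular-shift permutation p of 0.00737 to 0.0123, adjusted 0.0123). A candidate explanation is that some mutations inside a run of one base cannot be placed and are assigned or dropped by rule. In all 4 A runs of 3 or more, nucleotides from the third on also averaged less than the first 2, by -0.364. With 4 runs an exact sign-flip permutation test cannot go below the 0.125 it gave. In an A run of 3 the third nucleotide is the last one, so such runs say little about inner nucleotides. Pairing of the inner U stays open, because the sequence-only fold gave them a lower pairing probability (difference -0.162) but did not follow the Mbnl1 reactivities. Pairing and placement thus cannot be told apart here, and no biological explanation beyond pairing was tested.

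The uninduced profile stood apart from the induced ones, with a gap in mean r of 0.128. Taking each profile in turn as the lone one, 1 of 4 splits gave a gap that large and the highest other was -0.0364. The gaps of the 4 splits cancel out by construction, so the negative ones follow from the uninduced gap and are no separate evidence. Besides, 4 splits are too few for a share under 0.05. A63 is not the whole source, since a gap of 0.0606 was left without it. A different scale could not make a gap in r, because r ignores the scale of a profile. Ranks also ignore any distortion that keeps the order of values. In ranks the lowest rho of the induced pairs still exceeded the highest with the uninduced profile by 0.0353. Lower depth could not be excluded: the median deposited standard error of the uninduced profile was 0.838 of the highest induced one, but errors far below the replicate spread say little about depth. Induction of MBNL1 stays open beside an effect of doxycycline itself and a difference in sample handling. Among the Mbnl1 profiles only those of induced cells had doxycycline, so its own effect cannot be told from that of MBNL1. Nor can 1 uninduced profile tell either from sample handling.

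Several of the largest falls on induction crowded into the 50 nt upstream of the exon, where 7 of the 20 largest lay (A169, U171, U176, A178, G186, G189 and A197) and 2.46 would by even spread. No single induced profile accounts for it, as at least 6 of the 20 lay there without any of them. A loss of reactivity across the whole stretch stays open: relative to the rest its mean changed by -0.114 of the profile mean (exact permutation p of 0.344; -0.169 and 0.0943 without high-error nucleotides), while its median change was 0.0383, with 30 nt higher and 20 lower. Chance position remains a possible explanation, since 0.0541 of the circular shifts of the stretch held as many, and so does the tendency of any lone profile to give high values that fall back, since induced replicate 1 as the lone profile gave 5 (replicates 2 and 3 gave 1 each). Protection of single nucleotides such as U171, G186 and G189 by MBNL1 is therefore only a hypothesis. A further uninduced profile could show whether their high uninduced values repeat, but could not tell MBNL1 from doxycycline itself. The motif nucleotide G193 of the same stretch went the other way, from -0.00823 to 0.460 ± 0.120 (SD, n = 3). It did not pass in limma in the main setting, and was called, like U171, with rank-based scores.

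At A63 the uninduced profile also set the sum of its surroundings: nt 60 to 66 summed to 7.43 uninduced and 3.40 ± 0.464 (SD, n = 3) induced, and to 2.13 and 2.5997 ± 0.184 without A63 itself. In relative units A63 changed by -10.6, and the largest deviation of any single induced value from its induced mean was 2.70. That mean includes the value itself, which makes the deviation smaller than one from the other profiles. The change and the deviation are thus unlike measures.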
